A study of Drosophila melanogaster with 3 samples.

How the data were processed

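Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster pupae, aged 24 hours per the labels, from a fly line that stably carries the ecdysone receptor EcR fused at its C-terminus to enhanced GFP. Males and females were pooled. Chromatin was sheared by sonication, and an antibody against GFP was used, so the tagged receptor is what was targeted. DNA recovered without the tagged receptor was not measured here. There were 3 biological replicates from separate biosamples of that line, and they form the only group. No other stage, tissue, line or hormone treatment was analysed here, so no binding site can be said to be gained or lost.

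The values start from peak lists in the dm6 assembly. Per the deposited notes, each replicate list was derived from that replicate's alignment and a control alignment, a pooled list came from the alignments of all 3 replicates with that control, and an optimal list thresholded by the irreproducible discovery rate (IDR, a measure of how well peak ranks repeat between replicates) was derived from these. The control itself and the signal tracks were not used here. The aligner, the peak caller, its settings and the read numbers are not given in the sources used here, so the depth behind each peak is unknown and no counting interval is given. Each peak carries a signal value as deposited, which was used only to rank peaks within a list. The deposited −log10 q-value was at its maximum of 4.55 in all optimal peaks and could not rank them. Each of the replicate lists and the pooled list held exactly 30000 peaks, a fixed length that includes weak ones, so whole lists were not compared with each other. The optimal list held 9095 peaks, which were the 9095 strongest peaks of the pooled list, with the same intervals, summits and signals. They lay in 7569 regions, because 1281 wide regions held several summits (2807 in all).

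Positions are 1-based in dm6, which is release 6 of the D. melanogaster genome. The sequence and the Ensembl 115 annotation are of the same assembly, and 0 peaks ran past the end of a chromosome. All peaks lay on 2L, 2R, 3L, 3R, 4 and X. Each optimal summit was put in 1 class, in this order: promoter (within 500 bp of an annotated start of any gene other than a transposable element), 5′ UTR, 3′ UTR, coding exon, noncoding exon, intron and intergenic. Shares were compared with 1000 random placements on the same chromosomes by a two-sided permutation test. Random positions were drawn from all known bases, repeats included. A protein-coding gene was called bound when an optimal summit lay in its region, which is the gene body plus 2 kb upstream of the outermost start. Regions of neighbouring genes overlap, so 1 summit can count for several genes. For genes named below, such sharing is stated only in part. The share bound in each of 21 gene lists was compared with 10000 random lists in which every gene was replaced by one of the 200 protein-coding genes nearest in region length, two-sided. The strongest peak per gene was compared in the same way as a percentile of signal within the optimal list. Motifs were searched on both strands within 100 bp of each summit and in windows of the same width centred 1000 bp away. Shares were compared by an exact McNemar test against a side chosen at random, and arrangements of paired 6-base receptor sites with Fisher's exact test against both sides. Adjusted p-values are Benjamini-Hochberg values over 7 location classes, 21 lists, 11 motifs or 27 arrangements. For motifs at promoter peaks they are over the 11 motifs at promoter peaks and at other peaks together. For words of 7 bases they are over all 8192 words. Peaks and genes are not replicates, so these tests describe the combined list. Agreement between biological replicates was measured by comparing the 3 replicate lists and by repeating each result on the 9095 strongest peaks of each replicate. Replicate summits within 100 bp were counted as shared, and chance came from 100 random placements.

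The lists, motifs, tests and most alternatives were fixed before the data were examined. Named genes are every ecdysone response gene, the 15 strongest optimal peaks, and up to 3 bound members of each other list by their strongest peak. The lists covered ecdysone response, ecdysteroid synthesis and turnover, juvenile hormone, cell death, autophagy, neuronal remodelling and temporal identity, cuticle proteins, chitin and cuticle tanning enzymes, salivary glue and late puff genes, disc patterning, Hox, muscle, neuron, glia, fat body, gut digestive enzymes, haemocyte, testis, circadian clock, ribosomal proteins and chemoreceptors. Older symbols were matched to current ones, and every member was found among the 13945 protein-coding genes. Alternatives changed the number of peaks, the distance or overlap counted as shared, the replicates used, the promoter width, the gene region, the background, the mismatches, the window and the flanks. For location, genes, motifs and density, settings without 1 replicate kept optimal peaks with a shared summit among the 9095 strongest of both other replicates. These sets held 6706, 6681 and 6785 peaks without replicate 1, 2 and 3. The optimal list still came from all 3 replicates, so a call lost there can reflect fewer peaks and not dependence on 1 replicate. The computations were tested on 9095 simulated summits over the same 13945 genes. At random positions the promoter ratio was 1.05 and 0 lists passed. With 200 planted motif sites, 26 ecdysone response genes given a summit and 1000 summits placed at starts, all 200 sites were found, 28 of the genes were called bound with an adjusted permutation p of 0.0042, and the promoter ratio was 1.74. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.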

Results

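Binding of the ecdysone receptor, the nuclear receptor through which the moulting hormone ecdysone acts together with its partner ultraspiracle (usp), was mapped by anti-GFP ChIP-seq in whole pupae aged 24 hours. The data are 3 biological replicates of 1 line, EcR-GFP, with a peak list for each, a pooled list and an optimal list of 9095 peaks. The depth of the libraries is unknown. The optimal peaks had a median width of 565 bp and signals from 358 to 20268, with a median of 627.

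Binding recurred at the same places in the 3 replicates. Among the 9095 strongest peaks of each, 78.3% of summits were shared between replicates 1 and 2, 74.5% between 1 and 3, and 74.5% between 2 and 3. The mean was 75.8% ± 2.17 (SD, n = 3 pairs), against 1.37% by chance placement. Of the optimal peaks, 84.9% ± 1.12 (SD, n = 3 replicates) had a summit among a replicate's strongest. The share was 84.1%, 84.5% and 86.2% in replicates 1, 2 and 3, so no replicate stood apart. The optimal list was derived from these replicates, so that selection can raise these shares and the rank agreement across optimal peaks given below. The overlap between replicate lists does not depend on it. A strong summit was present in all 3 replicates for 6024 optimal peaks (66.2%), in 2 for 2100, in 1 for 900 and in none for 71. Ranks were compared across optimal peaks with a summit within 100 bp in both replicates of a pair. Across these peaks, which are not independent replicates, ranks in replicates 1 and 2 had a Spearman rho of 0.848 (8532 peaks). Replicate 3 had 0.772 with replicate 1 (8526 peaks) and 0.771 with replicate 2 (8515 peaks). The strongest peak was the same in all 3 replicates. It lay at 2L 2198414–2203951, with its summit at 2200425 in intergenic sequence, 2513 bp from the nearest start, that of COX7AL2.

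EcR-GFP lay mainly in introns and at promoters. Promoters held 3319 optimal summits (36.5%, against 13.6% of random placements, 2.68-fold), and introns held 4140 (45.5% against 39.4%). The 5′ UTRs outside promoters held 1.20% against 0.773%. Summits were less frequent than random placements in coding exons (2.47% against 13.1%), in 3′ UTRs (1.12% against 4.99%) and in intergenic sequence (12.3% against 27.4%). All of these had a permutation p of 0.002, the smallest that the placements can give, and an adjusted p of 0.00233. Random positions included repeats, and whether peaks can be called there was not taken into account, so the intergenic deficit need not be lower binding alone. Noncoding exons held 0.891% against 0.811%, which did not pass (adjusted permutation p = 0.448). In the 3 replicates' own lists the promoter share was 36.7% ± 1.47 (SD, n = 3) and the intron share 45.5% ± 1.06, so both departures from random were larger than the spread between replicates. The excess in 5′ UTRs was lost when promoters were taken as 1000 bp wide (0.495%, adjusted permutation p = 0.498).

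**Figure D1:**
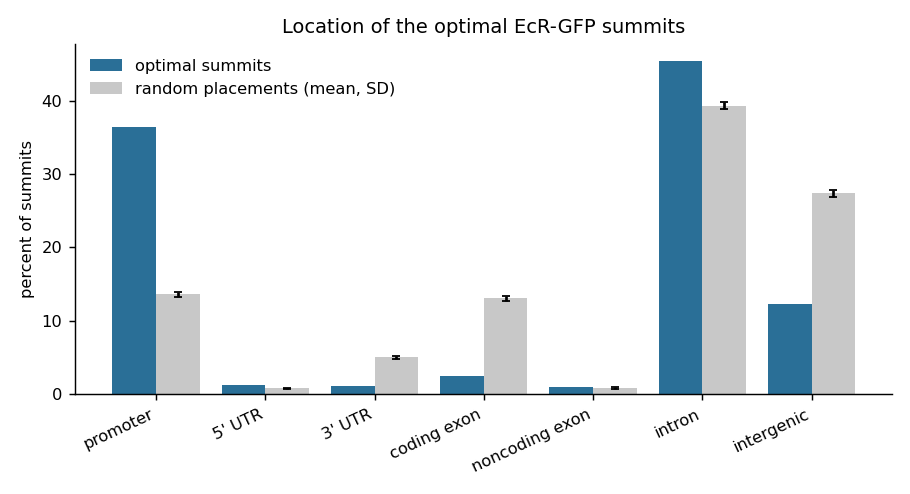
Percent of the 9095 optimal summits in each location class (blue bars) and the mean of 1000 random placements on the same chromosomes (grey bars, SD as error bars). Promoters hold 36.5% of summits against 13.6% at random, and coding exons 2.47% against 13.1%.

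The next comparison asked whether genes of the ecdysone response list are bound more often than other genes of their length. The list also holds parts of the signalling itself, such as the receptor's partner usp and the membrane receptor DopEcR. Of the 28 ecdysone response genes, 25 (89.3%) held an optimal summit, against 54.1% of length-matched genes (95% of random lists 35.7% to 71.4%; adjusted permutation p = 0.0042). In the replicates' own lists the share was 90.5% ± 2.06 (SD, n = 3). Across the genome 4281 protein-coding genes (30.7%) were bound. Some of these genes carried many summits, and others few or none. Eip75B (FBgn0000568, 3L 17950953–18064696), which encodes the nuclear receptor E75, held 83, more than any other protein-coding gene. EcR itself (FBgn0000546, 2R 6087873–6169087) held 43, the second highest number. Eip74EF, an Ets-domain factor, held 25, Hr4 24, Eip78C and br 18 each, tai 17, vri 16, Eip93F 14, and Hr3, E23 and ftz-f1 12 each. Wide regions hold several of these summits: with 1 summit per region, a setting chosen after the data were seen, Eip75B had 40, EcR 29, Hr4 14, br 11, Eip78C and vri 10 each, and Eip93F 9. Eip93F also fell to 9 on peaks shared without replicate 1 or without replicate 2. In the strongest 4547 optimal peaks Eip75B had 67, EcR 36, Hr4 17, Eip74EF 15, vri 14 and Eip78C 12. In the same peaks br and tai had 10 each, E23 9, Hr3 7, and Eip93F and ftz-f1 5 each. Over the full optimal list, only 134 genes in all held 10 or more. The list averaged 12.5 summits per gene, against 2.76 in length-matched lists, a comparison chosen after the data were seen (adjusted permutation p = 0.0021).

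The strongest peaks of many of these genes ranked high in the optimal list. The strongest peak of a bound ecdysone response gene lay at a median signal percentile of 98.2 (n = 25 genes), against 75.1 for bound genes of similar length, a difference of 23.1 (95% of random lists 57.3 to 87.2; permutation p = 0.0002, the smallest possible). Genes were matched on region length and not on the number of summits, which averaged 12.5 per listed gene against 2.76 in length-matched lists. The strongest of many summits ranks higher by number alone, so this difference is not separate from the summit counts. The second strongest optimal peak lay in an intron of vri, a bZIP repressor, at 2L 5289642–5294224 (signal 17827). Eip75B held the peaks ranked 3 and 4, both intronic, at 3L 18002777–18007006 (signal 16518) and 17990671–17994562 (signal 15395). Eip74EF held rank 6 in an intron at 3L 17610895–17612648 (signal 13006). EcR held rank 10 in an intron at 2R 6119725–6122880 (signal 11395) and rank 15 at 2R 6157875–6159615, where the summit lies 363 bp from the start of a noncoding gene and 1831 bp from the nearest EcR start. These 4 leading genes had their strongest peak within the first 16 ranks in every replicate. The strongest peaks of Hr4 (rank 19), Eip78C (46), tai (47), Sox14 (53), Hr3 (56), Hr39 (62), E23 (72), Kr-h1 (114), Blimp-1 (167), Eip93F (302), Eip63E (582), br (693), ImpL2 (984), ftz-f1 (1214) and crol (1659) were also intronic. Those of br and ImpL2 lie in regions shared with Mur2B and CG46460, and that of Hr3 in a region shared with CG12912 and CG46321. ImpE2 (rank 1350) and Hr38 (3668) had intergenic peaks upstream of the gene, and the ImpE2 peak also lies in the region of Eip63E. MsrA, earlier called Eip71CD (rank 2901), ImpE3 (5173) and usp (6064) had promoter peaks, those of ImpE3 and usp nearest to the starts of CG10903 and Actn. Eip63F-1 had 1 weak intronic peak (8789), which was absent from the peaks shared without replicate 1, 2 or 3. Cth (earlier Eip55E), DopEcR, a membrane receptor for ecdysteroids, and ImpE1 held no optimal summit.

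**Figure D2:**
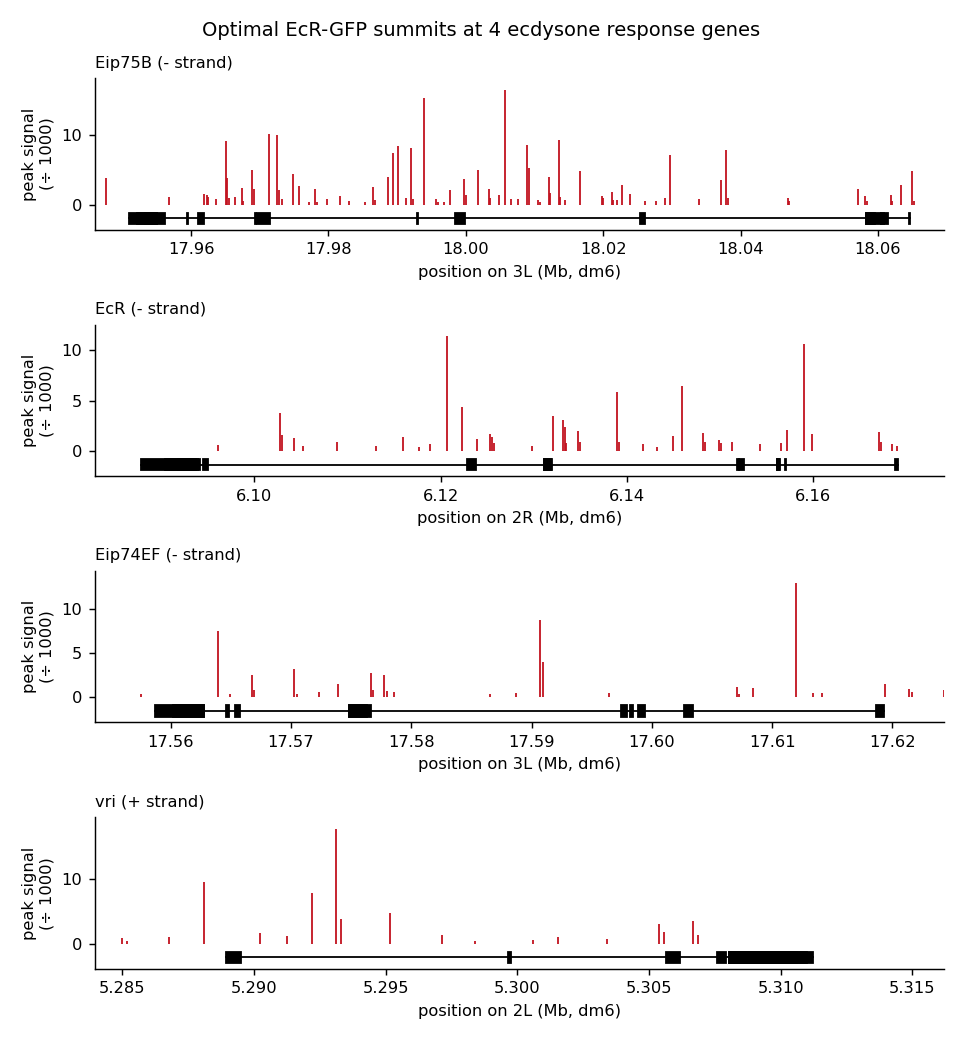
Optimal summits (red lines, height is the deposited peak signal divided by 1000) along Eip75B, EcR, Eip74EF and vri, each with 5 kb on either side. The x axis is the dm6 position in Mb, and black boxes are exons of all transcripts on the gene's span. The strongest summits, up to 17827 in vri and 16518 in Eip75B, stand in introns.

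Among the other 20 lists, 3 differed from length-matched genes. Of all 21 lists, 4 thus passed, against 11 without length matching, 7 when a summit within 1 kb of a start was required and 8 with 5 kb on both sides. Autophagy genes were bound more often, 15 of 20 (75%, against 36.4%; adjusted permutation p = 0.0056). Atg7 had a promoter peak at 2R 18624129–18625395 (rank 412), and Atg16 (rank 452) and Atg1, the kinase that starts autophagy (rank 581, 8 summits), had intronic peaks. The autophagy call did not hold on peaks shared without replicate 2 (55%, adjusted permutation p = 0.063) or without replicate 3 (50%, adjusted p = 0.227), nor in the strongest 4547 optimal peaks (25%, adjusted p = 1). It also did not hold for summits per gene (1.40 against 0.740, adjusted permutation p = 0.141). Neuron genes were bound less often, 4 of 20 (20%, against 59.7%; adjusted permutation p = 0.0063). Their strongest peaks were in introns of Dscam1 (rank 191) and Syn (911) and in a promoter at elav (3167) that lies nearest to the start of arg. The Syn peak also lies in the region of Timp, whose start is nearest to it. The neuron call was lost in the strongest 4547 peaks (adjusted permutation p = 0.0945) and without length matching (adjusted Fisher's exact p = 0.482). Chemoreceptor genes were also bound less often, 6 of 179 (3.35%, against 25.2%; adjusted permutation p = 0.0042). Or67a had a promoter peak (rank 117), and Gr93a (3019) and Gr93d (4238) had weaker intergenic peaks, each with a summit within 100 bp in only 1 replicate.

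The remaining 17 lists did not pass. Cell death genes were bound in 9 of 15 cases (60%, against 33.4%; adjusted permutation p = 0.13), with strong promoter peaks at the caspase gene Drice (rank 141) and at Dark (168), both shared with a neighbouring gene, and a coding exon peak at hid (474, 9 summits). The cell death list passed in the strongest 4547 peaks (adjusted permutation p = 0.0378), with starts within 1 kb (0.0112), and by Fisher's exact test without length matching (0.0417). It also passed in settings chosen after the data were seen, which were replicate 2's own list (adjusted permutation p = 0.0434) and summits per gene (2 against 0.704, adjusted p = 0.0147). Juvenile hormone genes were bound in 7 of 10 (70%, against 38.1%; adjusted p = 0.13 by permutation), led by tai, Kr-h1 and Jhbp1 (rank 535). The first pair also belongs to the ecdysone response list. Of the chitin and cuticle tanning genes 13 of 20 were bound (65%, against 43.6%; adjusted permutation p = 0.161), among them the chitin synthase kkv (rank 192) and the chitinases Cht7 (344) and Cht10 (778). Cuticle protein genes were bound in 18 of 122 cases (14.8%, against 18.9%, adjusted permutation p = 0.442), led by Cpr72Eb (rank 316), Cpr49Ac (477) and Cpr51A (503). The Cpr51A peak lies nearest to the start of CG30197. None of the 22 salivary glue and late puff genes was bound (against 13.1%; adjusted permutation p = 0.161). Ribosomal protein genes had 28 of 92 bound (30.4%, against 19.7%, adjusted permutation p = 0.0518), led by RpS19b (rank 162), RpS28a (660) and RpL17 (1740). The RpS19b peak lies nearest to the start of CG5854, and that of RpS28a also lies in the regions of Mgat2 and Axn. Gut digestive enzymes had 2 of 41 bound (4.88%, against 19.9%, adjusted permutation p = 0.0518), where Mal-A5 and Mal-A6 share 1 peak (rank 597). The ribosomal list passed with 5 kb on both sides (adjusted permutation p = 0.00105) and the digestive list with starts within 1 kb (0.0222), with 5 kb on both sides (0.0021) and by Fisher's exact test (0.000464). In settings chosen after the data were seen, both passed with 1 summit per region (adjusted permutation p = 0.0454 and 0.049) and in replicate 1's own list (0.022 and 0.035), and the digestive list in that of replicate 2 (0.0412). Muscle genes had 5 of 22 bound (22.7%, against 44.3%; adjusted permutation p = 0.13), led by Mef2 (rank 566), Zasp52 (1587) and Actn (3521). Muscle (adjusted permutation p = 0.0205) and glue genes (0.00105) passed with 5 kb on both sides, and chitin and tanning genes with starts within 1 kb (0.0136). Without length matching, juvenile hormone, neuronal remodelling, cuticle protein, chitin and tanning, glue and disc patterning genes also passed.

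Ecdysteroid synthesis and turnover genes were bound in 5 of 15 cases (33.3%, against 38.3%). Their strongest peaks lay at phtm, a cytochrome P450 of ecdysone synthesis (rank 49), at Oatp74D, the ecdysone importer (149), and at Eo (1738). Neuronal remodelling and temporal identity genes had 11 of 15 bound (73.3%, against 55.7%), with brat (rank 82, 23 summits), heca (293, 25 summits) and Mical (454). Circadian clock genes had 6 of 10 (60%, against 53.0%), with vri, sgg (rank 40) and cwo (1586). Disc patterning genes had 12 of 20 (60%, against 58.5%), led by hth (rank 1469), Delta (1609) and dpp (1823). Their share was 35%, 40% and 30% on peaks shared without replicate 1, 2 and 3, below matched genes in each case. Haemocyte genes had 6 of 13 (46.2%, against 45.7%), led by ush (rank 155, 24 summits), Hml (407) and srp (789). The ush peak lies nearest to the start of cbt. Fat body genes had 6 of 16 (37.5%, against 35.2%), led by the lipase gene bmm (rank 158), Lsd-1 (1788) and Apoltp (4531). Glia genes had 4 of 10 (40%, against 41.1%), led by Gli (rank 1558), Gs2 (3409) and moody (3947), and 20% on peaks shared without replicate 1 or without replicate 3. Hox genes had 3 of 8 (37.5%, against 59.5%), all with weak intronic peaks, at Scr (rank 5431), Antp (6641) and abd-A (7354), the last with a summit within 100 bp in replicate 3 only. Testis genes had 3 of 19 (15.8%, against 21.2%), at Mst87F (rank 1428), bam (1700) and comr (6377). The adjusted permutation p was 0.442 for neuronal remodelling, 0.545 for Hox and 1 for the other 7 of these 9 lists.

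**Figure D3:**
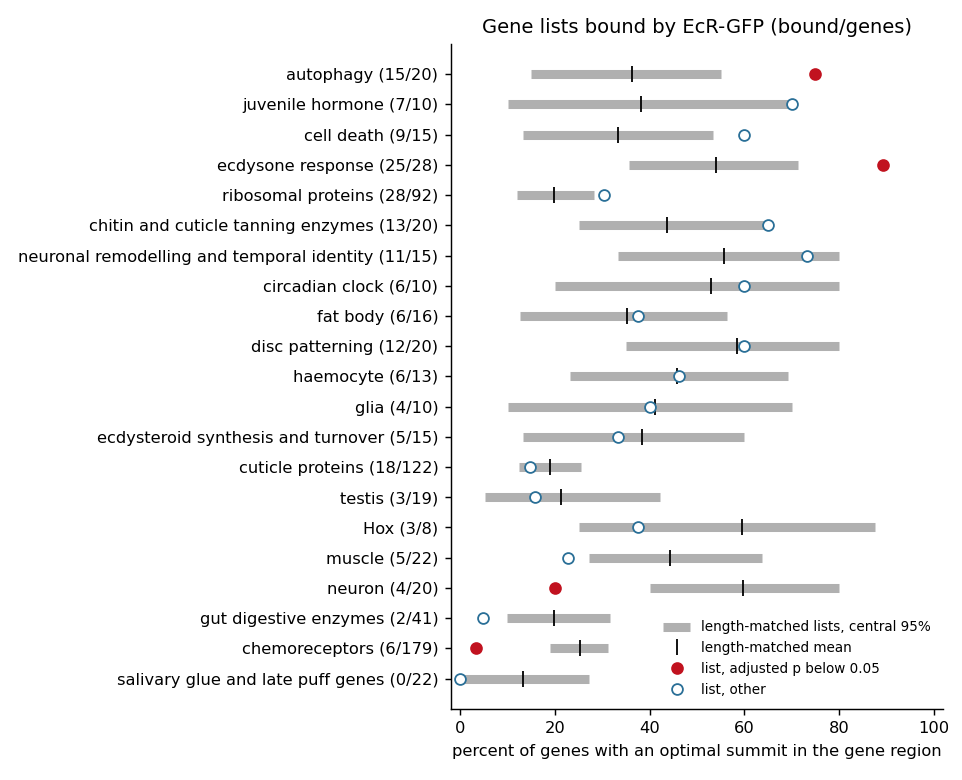
Percent of genes of each list with an optimal summit in the gene region (points; red for an adjusted p below 0.05), beside the mean (tick) and central 95% (grey bar) of 10000 length-matched lists. Ecdysone response (89.3%) and autophagy (75%) lie above their bars, and neuron (20%) and chemoreceptors (3.35%) below.

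Several of the 15 strongest peaks lay outside the regions of ecdysone response genes. COX7AL2 had rank 5 in its intron as well as the nearby rank 1. An intron of lama, in a region shared with CG46456, held rank 7 at 3L 5352230–5354913. Rank 8 was a promoter peak at 2L 2759418–2760341, 99 bp from a start of Tnpo-SR and also in the regions of HemK2 and Snapin. An intron of mam, which encodes the Notch coactivator mastermind, held rank 9 at 2R 14000433–14001300. Rank 11 lay 1436 bp from the start of CG43389, in intergenic sequence, and rank 13 at the promoter of CG30089. Rank 12, at 2L 12009915–12014649, was nearest among protein-coding genes to Rh5 at 5632 bp, and lies 482 bp from the start of a noncoding gene. Rank 14, at 2L 6078590–6079509, lay in an exon of a noncoding gene 3487 bp from a start of Kr-h1, an ecdysone response gene whose 2 kb upstream region it lies beyond.

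A known element of the EcR/usp pair is an inverted repeat of 6-base receptor sites with a spacer of 1 base. With at most 1 mismatch to RGKTCANTGAMCY, it was present at 440 optimal summits (4.84%, against 0.660% in flanks, 7.33-fold; adjusted exact McNemar p = 1.21e-73). In the replicates' own lists the share was 4.54% ± 0.606 (SD, n = 3) and the ratio 5.45 ± 0.404. The flank in that test is 1 side chosen at random; against both flanks together (0.797%), computed after the data were seen, the ratio was 6.07. It was 12 in a 50 bp window and 4.11 in a 200 bp window. The everted repeat of the same sites, a control for base composition, was at 0.473% against 0.308% (adjusted exact McNemar p = 0.132). This control passed in the own lists of replicates 2 (1.91-fold, adjusted exact p = 0.0265) and 3 (2-fold, adjusted exact p = 0.00822), and in a 50 bp window (2.23-fold, adjusted exact p = 0.0353), but not in that of replicate 1 (ratio 1). The share was 0.550% against 0.0990% with 0 mismatches and 18.6% against 6.72% with 2. The other 8655 peaks had no match within 100 bp, among them the strongest peaks of vri, Eip74EF and EcR. Of the 15 strongest peaks, 4 had a match. They were AGTTCACTGACAT in Eip75B (3L 17993935–17993947, 13 bp from the rank 4 summit), GGTTCATTGGCCC near Rh5, AGGTCAGTCAACC at CG30089 and CGGTCAATGAACC near Kr-h1. The strongest peaks of Hr3, E23 and Blimp-1 held GGGTCAATGCACC, AGTGCATTGAACC and AGTTCAATGACCG.

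The motif went with peak strength. It was present in 9.79% of the strongest 1819 peaks and in 2.58% of the weakest 1819, a ratio of 3.79 (Fisher's exact p = 3.19e-20), with 4.29%, 3.74% and 3.79% between. The ratio was 3.60 ± 0.254 (SD, n = 3) in the replicates' own lists. Among 27 arrangements of exact paired sites, the inverted repeat with spacer 1 was 5.26 times as frequent at summits as in flanks (50 peaks, adjusted Fisher's exact p = 7.79e-10). Direct repeats with spacer 0 were 9.25 times as frequent (37 peaks, adjusted Fisher's exact p = 5.41e-10), those with spacer 4 were 2.89 times (26 peaks, adjusted p = 0.00525), and those with spacer 6 were 3.11 times (14 peaks, adjusted p = 0.0492). The other 23 arrangements did not pass. In windows of 200 bp the ratio of the inverted repeat was 3.13, and outside promoters, a setting chosen after the data were seen, it was 8.

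**Figure D4:**
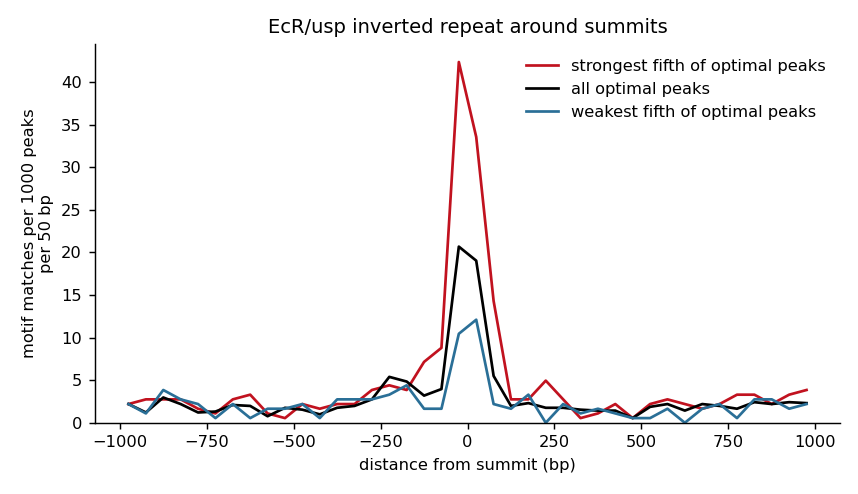
Matches to the EcR/usp inverted repeat (at most 1 mismatch) per 1000 peaks in bins of 50 bp, against the distance from the summit in bp, for all 9095 optimal peaks (black) and for the strongest (red) and weakest (blue) 1819. Distances follow genome coordinates, without regard to strand. In the 50 bp below the summit there are 42.3 matches per 1000 for the strongest peaks and 10.4 for the weakest. In the 50 bp above it there are 33.5 and 12.1.

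Several sites other than the EcR/usp element were also more frequent at summits than in flanks. Summit windows held more G and C (46.1% against 42.7% on both sides), which these tests did not take into account. GAGA, the site of the GAGA factor, was at 10.6% of summits (2.80-fold; adjusted exact McNemar p = 7.14e-74), and the grainyhead site at 1.22% (4.11-fold, adjusted p = 9.95e-13). The single receptor site AGGTCA was at 7.77% against 5.51% (adjusted exact p = 2.66e-09) and the ftz-f1 site at 1.87% against 0.968% (adjusted p = 7.29e-07). AGGTCA is a form of the 6-base site in the EcR/usp element, and summits with that element were not removed before counting. AP-1 was at 2.95% against 2.28% (adjusted exact p = 0.00793), a call lost in the strongest 4547 peaks (adjusted p = 0.0576), on peaks shared without replicate 3 (0.0502) and in a 50 bp window (0.0897). The DNA replication-related element DRE was at 0.935% against 0.473% (adjusted exact p = 0.000422), and this did not hold against random positions of the same location class (adjusted p = 0.405) or on peaks shared without replicate 1, 2 or 3 (adjusted p = 0.258, 0.374 and 0.14). It was also lost in the strongest 4547 peaks (adjusted exact p = 0.0576), in replicate 3's own list (0.0782) and outside promoters (0.583). Zelda (1.10% against 1.32%), Ets (0.0880% against 0.121%) and E-box (2.62% against 2.91%) sites did not pass (adjusted exact p = 0.234, 0.648 and 0.264). Zelda sites passed, below flanks, in replicate 3's own list (0.702-fold, adjusted exact p = 0.0129) and at promoter peaks (0.904% against 1.72%, adjusted exact p = 0.011), both settings chosen after the data were seen. At promoter peaks AGGTCA (6.09% against 6.06%), ftz-f1 (1.14% against 1.60%), grainyhead (0.753% against 0.482%) and AP-1 (2.26% against 1.75%) sites did not pass (adjusted exact p = 1, 0.266, 0.332 and 0.297).

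Peaks were spread over all arms. There were 75.2 optimal peaks per Mb on 3L, 71.8 on 2R, 69.6 on 3R, 65.0 on 2L, 59.8 on X and 9.01 on 4, where only 12 peaks were called. Peak density on X was 0.848 of that on 2L, 2R, 3L and 3R together, and 0.847 ± 0.0442 (SD, n = 3) in the replicates' own lists. Males and females were pooled, and the number of copies of X was not taken into account.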

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

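Pooled peaks ranked below the optimal list, which enter no comparison above, still carried the EcR/usp motif more often than their flanks: 1.75% of 20905 peaks against 0.713%, a ratio of 2.45 (exact McNemar p = 4.06e-22). The test was chosen after the data were seen. The share was below the 2.58% of the weakest optimal peaks. Among the 3 ecdysone response genes without an optimal summit, ImpE1 held 7 of these weaker summits, Cth 2 and DopEcR 0.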

How the results depend on the processing

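Settings with 1 summit per region, a replicate's own list, peaks outside promoters or summits per gene, and all alternatives for chromosome density, were chosen after the data were seen. Under every alternative run, the promoter share (27.8% to 47.8%), ecdysone response genes bound (78.6% to 96.4%, or 12.5 summits per gene), their peak strength (difference 22.7 to 28.6), the EcR/usp motif share (0.550% to 18.6%), its ratio by strength (2.72 to 4.18) and the inverted repeat with spacer 1 (3.13 to 8) kept their direction and passed the test. The ratio of the motif share to flanks ran from 2.77 with 2 mismatches to 12 in a 50 bp window. The strongest 9095 pooled peaks are the optimal list itself, so that alternative was void. Depth is unknown and limits were not computed.

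Replicate overlap was 78.6% with 4547 peaks, 73.0% with 18190 and 61.2% for summits within 50 bp, and 74.5% to 78.3% without 1 replicate. Optimal peaks found per replicate were 47.9% with 4547 peaks, where about 50% is the most possible, 96.1% with 18190, 76.4% within 50 bp and 77.9% with reciprocal overlap of 50%. Lists past the threshold numbered 11 with Fisher's exact test without length matching, 7 with starts within 1 kb and 8 with 5 kb on both sides. X density was 0.748 of that on 2L, 2R, 3L and 3R in the strongest 4547 peaks, 0.797 in replicate 1's own list, and 0.797 to 0.849 without 1 replicate. Where no reason is given, the cause was not tested.

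In 46 comparisons of single lists, classes or motifs the direction turned. The main value had passed its test for DRE alone, which outside promoters was at 0.329%, below flanks. In the strongest 4547 peaks these were noncoding exons (0.770%), ecdysteroid synthesis (26.7%), disc patterning (25%), glia (30%), fat body (18.8%), haemocyte (23.1%) and ribosomal proteins (8.70%). Without 1 replicate, disc patterning (30% to 40%) and E-box (2.5% to 2.62%) turned in each of the 3 settings. The following turned in some of the 3, and their ranges cover all: noncoding exons (0.737% to 0.898%), glia (20% to 40%), haemocyte (38.5% to 46.2%) and ecdysteroid synthesis (26.7% to 33.3%). In own lists they were disc patterning (50% in replicate 1, 40% in 2), circadian clock (50% in both), E-box (2.64% and 2.68%) and fat body (31.2% in 2 and 3). With Fisher's test they were ecdysteroid synthesis (33.3%), Hox (37.5%), glia (40%) and ribosomal proteins (30.4%); with starts within 1 kb, ecdysteroid synthesis (33.3%), haemocyte (30.8%) and ribosomal proteins (23.9%); with 5 kb, ecdysteroid synthesis (60%), glia (80%), haemocyte (53.8%) and circadian clock (60%). The others were Ets with 1 summit per region (0.0793%), noncoding exons with 1000 bp promoters (0.374%), fat body by summits per gene (0.625), Zelda outside promoters (1.21%), and E-box in a 200 bp window (5.33%), with flanks at 2000 bp (2.62%) and against random positions of the same class (2.62%). Of the other single results, 28 newly passed, 16 no longer passed, 40 counts of summits moved by over 1.5 times and 561 kept their direction and call or, for counts of summits, stayed within 1.5 times. These include the void alternative, and their values could still move.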

Other observations

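The tests of the 2-mismatch element, of the single extended site, of location by strength, of motifs by location, of starts of protein-coding genes beside tRNA genes, of 7-base words and of density outside the optimal list were chosen after the related results were seen. Some genes outside the fixed lists held more summits than most ecdysone response genes, though fewer than Eip75B (83) and EcR (43): jing 32, Tet 29, shn 26, Glut4EF 25, tara and sbb 24, E2f1 23 and Mnt 21. Relative to region length, Eip75B had 7.17 summits per 10 kb, Mnt 6.59, tara 6.54, E2f1 5.40 and EcR 5.17. Of 8192 words of 7 bases counted with their complements, 1639 were more frequent at summits than in both flanks and 1701 less frequent, at an adjusted Fisher's exact p below 0.05. Ranked by p, the leading ones among the more frequent were of the GAGA kind (CTCTCTC at 10.6% of summits against 3.82%), followed by CACACAC at 14% against 7.47%. CTCTCTC also led by ratio (2.76-fold), where CACACAC was lower (1.87-fold). Summit windows were 46.1% G and C, against 42.7% on both sides.

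Promoter peaks and other peaks carried different sites. The EcR/usp motif was at 2.65% of promoter summits and 6.09% of others, grainyhead at 0.753% and 1.49%, and ftz-f1 sites at 1.14% (below the 1.60% of flanks) and 2.29%, while DRE was at 1.99% and 0.329% and GAGA at 12.8% and 9.28%. Of these differences, that of the EcR/usp motif was tested and passed, and the others were not tested. Promoters held 33.3% of the strongest 1819 peaks and 38.4% of the weakest (Fisher's exact p = 0.00147). Peak density on X relative to 2L, 2R, 3L and 3R was 1.08 in the weaker pooled peaks, against 0.848 in the optimal list.

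Most optimal peaks lacked the EcR/usp motif. Peaks without it were in promoters in 37.3% of cases and peaks with it in 20%. The difference was 17.3 points (Fisher's exact p = 2.10e-14). This was foreseen if part of the signal arose at open promoters without the inverted repeat. Openness was not measured, and peaks without the inverted repeat can hold other paired sites, such as the direct repeats above. Signal at open promoters may account for some of the 8655 peaks without the motif, but 5424 of them lay outside promoters. Elements with 2 mismatches were at 14.5% of these peaks against 6.44% in flanks, an excess of 8.02%, so most of these peaks lacked such an element. The bound for this explanation was set after the 2-mismatch share of all peaks had been seen, so it was not a prediction. Elements with more mismatches were not counted. Binding through other proteins and other elements was not tested, and the control was not used here, so recovery without EcR stays open.

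Strong peaks at the EcR locus could come from extra copies carried by the transgene. The planned comparison used the 32 pooled summits in EcR outside the optimal list, whose median signal percentile lay above that of 42.2% of 128 gene regions of similar length. It decides nothing, because the optimal list is the strongest part of the pooled list, so summits raised by extra copies would have left the set compared. Extra copies therefore stay open, and so does binding of the receptor at its own gene, which was not tested against them.

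Optimal summits lay within 250 bp of tRNA genes 23 times, against 9.82 ± 3.19 (SD) in random placements, a ratio of 2.34 (permutation p = 0.002, the smallest possible). That ratio is past the 2 set beforehand for non-specific recovery of highly transcribed genes. It cannot point to that cause, because summits were enriched at starts of genes in general. The ratio at starts of protein-coding genes was 4.02, so tRNA genes did not exceed promoters at large. Of the 28 tRNA genes with a summit, only 6 had a protein-coding start within 500 bp, so such starts do not account for most of them. Among all 290 tRNA genes, 33 had such a start. Ribosomal protein genes were not part of this test. Transcription was not measured here, so non-specific recovery and binding by the receptor at tRNA genes both stay open.

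Direct repeats with spacer 0 were looked at further because they had the highest ratio of the arrangements that passed. None of the 37 sites lay in an annotated transposable element or had a near-identical neighbourhood at another site (0%). These 37 sites were thus not near-identical copies of 1 repeated sequence. Whether peaks can be called in repeats is unknown, so the test says nothing about sites in repeats that were not called. The bound for this explanation was set before that test, though after the excess was seen. Of the 37 sites, 6 contained TCAAGGTCA, a form of the ftz-f1 site. Outside such repeats, TCAAGGTCA was 2.36 times as frequent at summits as in flanks (95% bootstrap interval 1.5 to 3.86), below the interval of the repeat (4.77 to 26.7), and the general form TCARGKTCA was 2.28 times as frequent (1.79 to 2.89). Single extended sites may add to the excess but do not reach it. Which receptor binds the repeat was not tested.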
